A study of Mus musculus with 9 samples.

How the data were processed

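RNA sequencing of mouse colon was analysed in 9 libraries from 3 groups of 3: untreated wild-type mice (Blank), wild-type mice given dextran sulfate sodium, a detergent-like polymer that injures the colon lining (DSS; the group Model), and mice given DSS together with carbon dots from lotus node charcoal (the group CDs). Groups and replicate numbers come from the sample titles. The series description states that replicates are biological. Doses, schedules and the day of collection are not given in the sources used here.

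Per the labels' protocols, total RNA was extracted with Trizol, poly-A RNA was captured on oligo-dT beads, fragmented and copied into cDNA with random primers, and the adapter-ligated fragments were amplified by PCR before sequencing. That protocol has no step that marks the strand, and the strand setting of the counting is not given in the sources used here, so genes that overlap another gene, on either strand, are uncertain. Reads of near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, members of the Reg3 family and of the pancreatic trypsin family) could be split between them by the counting and are uncertain one by one. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1 were used. The genome build is not given in the sources used here. Of the 21959 genes in the table, 21851 had their identifier in the GENCODE annotation release 21 of GRCm38, but 501 of these (2.29%) had the same start and end there, so coordinates are printed as the deposited table gives them, with no build assigned. By that annotation 99.4% of the matched genes were protein-coding.

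Per the file headers, the authors deposited a read count and an FPKM value for each gene and library, with gene positions, lengths and pathway names. The counts were whole numbers with a different total in each library. The deposited FPKM values equalled count divided by gene length and by the library's total count in 100% of values, to a relative tolerance of 1e-06. They thus hold no information beyond the counts and gene lengths. They were used only in 1 alternative and in the rule for named genes, both given below. A total of 3565 genes had no read in any library. Another 95 genes had no symbol of their own and were kept under their identifier.

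Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, in R 4.3.3) in 1 fit of all 9 libraries with 1 coefficient per group, after the edgeR expression filter (14921 genes tested) and TMM scaling. P-values were two-sided and adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 are referred to as called. Fold changes are log2 ratios between group means. Their standard error (SE) was the fold change divided by the square root of the F statistic. Group means are in CPM, the read count scaled to the library size, after TMM scaling, with the standard deviation (SD) over 3 libraries. A group with no read is given as a bound that assumes 3 reads per library. The comparisons were Model versus Blank, CDs versus Model and CDs versus Blank.

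Gene lists of cell types and pathways, 41 in all, were fixed before the data were examined, as were the tests and most alternatives. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way. P-values were adjusted over the 41 lists. For some lists, counts of members called are also given adjusted over the list alone. The rule for named genes took, for Model versus Blank and for CDs versus Model, the 10 genes with the highest and the 10 with the lowest fold change among called genes with a mean deposited FPKM of at least 5 in 1 of the groups, groups that did not overlap and an established symbol, plus for each list the 3 members with the smallest p in Model versus Blank and the 2 with the smallest p in CDs versus Model. Other genes are named as chosen after their values were seen. Pathways written in the deposited table were tested among called genes with a one-sided Fisher's exact test against the 6235 tested genes that carry a pathway, for pathways of 10 to 300 genes. This test was added after the data were examined, as were the lists of prostate, pancreatic islet, platelet and mesothelial genes.

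The test was checked on simulated counts drawn from the means and library sizes of the real libraries, with 50 genes changed at each fold size. Each gene was drawn independently, so the simulated libraries lack variation that many genes share. For CDs versus Model, simulated on 14805 genes, it recovered 4% of 1.5-fold, 46% of 2-fold, 72% of 3-fold and 96% of 4-fold changes, with 6 false calls among 115. For Model versus Blank, simulated on 14833 genes, the shares were 12%, 42%, 76% and 82%.

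The alternatives were the replicate number as a block, a fit of the 6 libraries compared, each library left out in turn, no filter and a filter of at least 50 reads in at least 3 libraries, RLE size factors, DESeq2 1.42.0, limma on log2(FPKM + 1), a fold change limit, and, added after seeing the data, fits without the libraries holding pancreatic or prostate transcripts and a fit with the pancreatic level as a covariate. The replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated between -0.37 and 0.21 across genes. Alternatives planned for a table without counts did not apply. Figures were drawn with matplotlib 3.10.9.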

Results

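Transcript levels were measured by poly-A RNA sequencing in the colon of 3 untreated mice (Blank), 3 mice given the colitis-inducing polymer DSS (Model) and 3 mice given DSS and lotus node charcoal carbon dots (CDs). Carbon dots are nanometre-sized carbon particles. Libraries held 13868864 to 19940300 counted reads, and 16612 to 17120 genes had at least 1 read. A gene with no read in a library could have been present at up to 0.150 to 0.216 CPM (3 reads), a limit that covers counting error only.

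The libraries separated first by DSS. The first principal component held 66.2% of the variance and placed the Blank libraries between -87.1 and -77.5 and the 6 DSS-treated libraries between 11.7 and 63.2. The mean Euclidean distance was 145.6 between Blank and Model, 128.7 between Blank and CDs and 80.8 between Model and CDs, beside 82.1 within Model, 71.3 within CDs and 56.9 within Blank. The distance between Model and CDs libraries thus lay between the distances within CDs and within Model.

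**Figure D1:**
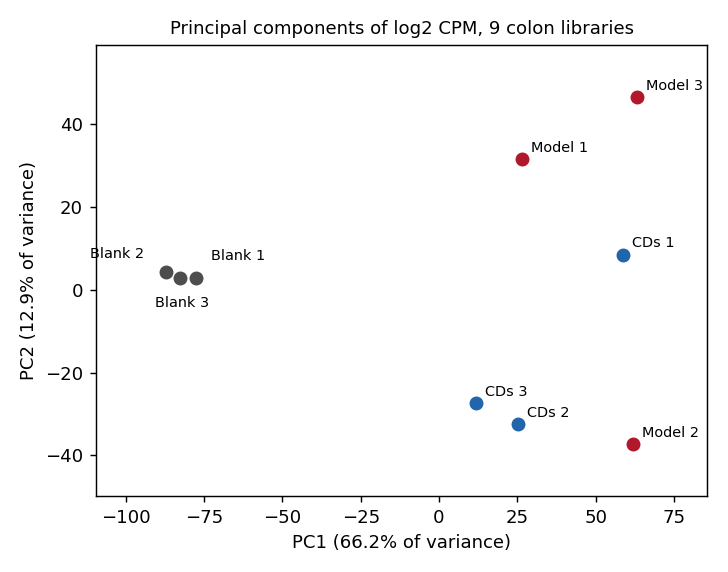
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library (grey, Blank; red, Model; blue, CDs). The 3 Blank libraries lie together at the left, and Model and CDs libraries are interspersed at the right.

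The first comparison, Model versus Blank, asks which transcripts differed in DSS-treated colon. Of the gene lists, 15 of 16 inflammatory cytokines, 19 of 21 neutrophil markers and 15 of 15 metalloproteinases and inhibitors rose, and 10 of 15 stem cell, 14 of 24 cell cycle and 22 of 28 oxidative phosphorylation genes fell. Il6, a cytokine (ENSMUSG00000025746, chromosome 5, 30218112 to 30224979), was at 0.113 ± 0.0344 CPM in Blank and 37.9 ± 21.6 CPM in Model (SD, n = 3 each), a log2 fold change of 8.28 ± 0.83 (SE; edgeR adjusted p = 3.14e-04). Lgr5, a marker of intestinal stem cells, fell from 14.9 ± 2.67 to 1.08 ± 0.412 CPM (SD, n = 3 each), a log2 fold change of -3.80 ± 0.37 (SE; edgeR adjusted p = 2.97e-04). Across 14921 genes, 6574 were called (44.1%), 3654 higher and 2920 lower in Model, and with a fold change of at least 2 in addition 3417 were called, 2453 higher and 964 lower. The groups did not overlap for 61.0% of the tested genes, beside 10% by chance. Counts of list members called are to be read beside the 3654 higher and 2920 lower of all 14921 genes. Lists near the share called higher, which do not stand out by their count, include unfolded protein response (5 of 21), interferon-stimulated (8 of 27) and smooth muscle genes (4 of 18).

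Neutrophil markers rose in 19 of 21 tested members and fell in 1 (19 and 1 adjusted over the list alone). Cxcr2, a chemokine receptor of neutrophils (chromosome 1, 74193148 to 74200405), had a log2 fold change of 9.60 ± 0.95 (8.82 without Model 2), Csf3r of 4.24 ± 0.34 and Mmp9 of 4.85 ± 0.55. S100a8, a calcium-binding protein abundant in neutrophils, went from 0.164 ± 0.0865 to 253 ± 337 CPM (SD, n = 3 each), with 37.9, 641 and 80.4 CPM in Model 1, Model 2 and Model 3. S100a9, its partner protein, had a log2 fold change of 9.16 ± 1.26, and of 7.35 without Model 2. Stfa2l1, of the stefin family of protease inhibitors, had no read in Blank and 1.31, 19.1 and 3.15 CPM in Model 1, Model 2 and Model 3, and was at least 39.2-fold higher in the mean of Model and at least 11.1-fold higher without Model 2. Monocyte and macrophage markers rose in 19 of 20 members, among them Cd68 (log2 fold change 2.44 ± 0.14) and Fcgr1 (3.26 ± 0.30). Inflammatory cytokines rose in 15 of 16 members, with Il11 at 7.70 ± 0.83, Il33 at 4.07 ± 0.30 and the granulocyte growth factor Csf3 at 8.64 ± 1.32 (10.59 without Blank 2 and 7.83 without Model 2), and chemokines rose in 15 of 20 and fell in 1 (16 and 1 adjusted over the list alone). Cxcl5, which attracts neutrophils, had a log2 fold change of 6.07 ± 0.57. In limma's camera test the adjusted p was 1.14e-08 for neutrophil markers, 2.22e-10 for monocytes and macrophages, 5.95e-08 for cytokines and 3.91e-07 for chemokines, and for each of the 4 lists adjusted p = 0.346 with an estimated correlation.

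The NF-kB and Toll-like receptor list rose in 18 of 24 members (22 higher and 1 lower adjusted over the list alone), with Tlr13 at 3.12 ± 0.32 and Ptgs2, the inducible cyclooxygenase, at 4.44 ± 0.74 on the log2 scale. The JAK-STAT3 list rose in 13 of 18 and fell in 1, with Osmr at 3.05 ± 0.19 and Socs3 at 3.68 ± 0.35. Both lists were called by camera (adjusted p = 5.90e-07 and 3.58e-05; adjusted p = 0.346 with an estimated correlation for both). Inflammasome genes went both ways: 5 of 18 rose, among them Nlrp3 (3.61 ± 0.43), and 3 fell, among them Pycard (-1.35 ± 0.23), and the list was not called (camera adjusted p = 0.834), with a median of -0.36 and a mean of 0.06. Interferon-stimulated genes rose in 8 of 27 members, with Gbp5 at 2.64 ± 0.39 (camera adjusted p = 0.00429; adjusted p = 0.528 with an estimated correlation). Without Model 1 its camera adjusted p was 0.0619.

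Lymphocyte lists rose in part. T cell markers rose in 6 of 19 members and B cell markers in 8 of 13 (9 adjusted over the list alone), while plasma cell markers rose in 2 of 7 and that list was not called (camera adjusted p = 0.188). Mast cell and eosinophil markers rose in 6 of 12 and fell in 1, and enteroendocrine and tuft cell markers rose in 10 of 18 and fell in 2. Camera adjusted p was 0.00782 for T cells, 0.00275 for B cells, 0.0339 for mast cells and eosinophils and 0.0136 for enteroendocrine and tuft cells. With an estimated correlation adjusted p = 0.522 for T and B cells and adjusted p = 0.346 for the mast cell and eosinophil and the enteroendocrine and tuft cell lists. Without Model 3 the mast cell and eosinophil list had a camera adjusted p of 0.0514.

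All 15 tested matrix metalloproteinases and inhibitors were called higher, including Mmp3 (log2 fold change 7.86 ± 0.57), Mmp10 (7.53 ± 0.60) and Timp1 (4.82 ± 0.41). Extracellular matrix and fibroblast genes rose in 25 of 26 members, endothelial markers in 17 of 18 with Selp at 5.29 ± 0.34, enteric neuron and glia markers in 17 of 18 with Gfap at 2.81 ± 0.25, and coagulation and fibrinolysis genes in 17 of 22 with F10 at 5.04 ± 0.53. Adipocyte markers rose in 8 of 11 members, with Fabp4 at 1.89 ± 0.21. Smooth muscle markers rose in 4 of 18 and the list was not called (camera adjusted p = 0.778). The camera adjusted p was 1.77e-10 for metalloproteinases, 5.35e-11 for matrix, 3.06e-10 for endothelium, 3.91e-07 for neurons and glia, 1.50e-05 for coagulation and 0.00161 for adipocytes, and with an estimated correlation adjusted p = 0.346 for the first 5 and adjusted p = 0.458 for adipocytes.

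Epithelial genes fell in part. Of 15 intestinal stem cell genes 10 fell and 2 rose, with Axin2 at -2.24 ± 0.27 and Ephb3 at -1.69 ± 0.18 on the log2 scale. Of 24 cell cycle genes 14 fell and none rose (15 adjusted over the list alone), with Plk1 at -1.53 ± 0.26. Goblet cell and mucin genes fell in 7 of 21 members and rose in 1, including the secretory-lineage transcription factors Atoh1 (-1.92 ± 0.34) and Spdef (-1.33 ± 0.27). Absorptive colonocyte genes fell in 10 of 26, including the transcription factor Cdx2 (-1.78 ± 0.39). Tight junction genes fell in 10 of 20 and rose in 1, with Cldn15 at -2.30 ± 0.37 and Cldn1 at 2.73 ± 0.42 (3.34 without Blank 2). Wound-associated epithelial genes rose in 10 of 19, with the growth factor Ereg at 6.28 ± 0.59. Camera called the stem cell (adjusted p = 0.00245), cell cycle (9.27e-04), goblet (0.00659), absorptive (8.47e-04), tight junction (0.00122) and wound (0.00574) lists. With an estimated correlation adjusted p = 0.346 for the stem cell and wound lists and adjusted p = 0.522 for the other 4.

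Of 28 oxidative phosphorylation genes 22 fell and none rose, with Ndufs1 at -0.94 ± 0.13 (camera adjusted p = 2.93e-08; adjusted p = 0.458 with an estimated correlation). Of 13 mitochondrially encoded genes 6 fell (camera adjusted p = 0.00473; adjusted p = 0.522 with an estimated correlation), and the reads of mitochondrially encoded genes made up 6.64% ± 0.0370 of each library in Blank and 4.20% ± 0.637 in Model (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). PPAR and fatty acid oxidation genes fell in 15 of 24 members and rose in 3, with Acat1 at -1.04 ± 0.16 and Angptl4 at 4.69 ± 0.29 (camera adjusted p = 0.00489; adjusted p = 0.522 with an estimated correlation). Large falls among genes named by the rule included Cps1, the first enzyme of the urea cycle (-5.01 ± 0.58), Nxpe2 (-4.59 ± 0.44), A4gnt, a mucin glycosyltransferase (-4.36 ± 0.61, and -5.04 without Model 1 and -3.77 without Model 2), the glutathione transferase Gstm3 (-4.06 ± 0.59) and the epithelial NADPH oxidase Nox1 (-3.97 ± 0.83).

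Redox, stress and defence lists went both ways. Enzymes that produce reactive oxygen species rose in 9 of 15 members and fell in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00950; adjusted p = 0.458 with an estimated correlation). Antioxidant and NRF2 target genes rose in 7 of 29 and fell in 8, with Gstm1 at -1.53 ± 0.14, and that list was not called (camera adjusted p = 0.315), its median being -0.24 and its mean 0.11. Ferroptosis and iron handling genes rose in 8 of 18 and fell in 3, and were not called (camera adjusted p = 0.118). Xenobiotic metabolism genes fell in 9 of 24 and rose in 4, with the sulfotransferase Sult1a1 at -2.90 ± 0.48 (camera adjusted p = 0.0339; adjusted p = 0.522 with an estimated correlation). Antimicrobial and acute phase genes rose in 12 of 21 and fell in 4, with haptoglobin, Hp, at 6.94 ± 0.77 and at 6.13 without Model 2 (camera adjusted p = 0.0235; adjusted p = 0.346 with an estimated correlation), and without Model 1 the camera adjusted p was 0.0558. Unfolded protein response genes rose in 5 of 21 (camera adjusted p = 0.0195; adjusted p = 0.346 with an estimated correlation) and hypoxia and glycolysis genes rose in 8 of 21 and fell in 1 (camera adjusted p = 0.0418; adjusted p = 0.522 with an estimated correlation), the last with a camera adjusted p of 0.0625 without Blank 2 and 0.110 without Model 2. Immediate early, squamous epithelium and skeletal muscle lists were not called (camera adjusted p = 0.0814, 0.323 and 0.834).

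Transcripts of other organs were present in some libraries. Pancreatic acinar genes took 6.86% of reads in Model 3, 0.833% in Model 1 and 0.0364% in CDs 1, beside 0.0157% to 0.0220% in Blank, 0.00279% in Model 2 and 0.0145% and 0.0136% in CDs 2 and CDs 3. Outside Model 1, Model 3 and CDs 1 most of these reads were of Cela1 (2433 of 2522 in Blank 1 and 480 of 557 in Model 2). There Cpa1, Cela2a, Cela3b and Pnlip had no read. Reg1, Serpini2, Reg3d, Cpb1 and Gp2, all known from the pancreas, were among the 10 highest fold changes that met the rule for named genes, which asks that the groups do not overlap. Pnlip and Cpa1 had higher fitted fold changes but no read in Model 2, so that their groups overlapped. In all 11 of 12 acinar genes were called higher (12 adjusted over the list alone), the groups not overlapping for 1 of them, beside 10% by chance. The list's camera adjusted p was 0.0136 (adjusted p = 0.522 with an estimated correlation), and 0.0677 without Model 3 and 0.0558 without Model 1. Reg1, Serpini2 and Reg3d had no read in Blank. In Model 2 they were at 0.047, 0.047 and 0.095 CPM, under the limit of 0.150 CPM (3 reads) in that library. Only values under that limit kept their groups from overlapping, and their means in Model came from Model 1 and Model 3. In the mean of Model they were at least 3655-fold, 358-fold and 337-fold higher. Without Model 3 these bounds were 648-fold, 48.3-fold and 47.4-fold, and each gene lost its call without Model 3 and without any single Blank library, Serpini2 and Reg3d also without CDs 1, and Cpb1 without any single Blank library. The prostate gene Tgm4, the lowest log2 fold change among the named genes (-7.31 ± 1.72; edgeR adjusted p = 0.00939), was at 602.5 and 56.4 CPM in Blank 2 and Blank 3 and at 2.19 CPM in Blank 1, and had a log2 fold change of -4.38 without Blank 2. Without the 3 libraries with pancreatic transcripts the sign of Ctrl and Clps turned, and without Blank 2 and Blank 3 the number of called genes was 1536 (1218 higher, 318 lower), with 1 Blank library left, which is assumed to vary like the other groups. In that fit camera no longer called the interferon-stimulated (adjusted p = 0.331), T cell (0.477), B cell (0.102), mast cell and eosinophil (0.0864), reactive oxygen species (0.106), hypoxia and glycolysis (0.0923) and erythroid (0.0763) lists. Without the 3 libraries with pancreatic transcripts it no longer called the interferon-stimulated (adjusted p = 0.891) and antimicrobial (0.140) lists.

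**Figure D2:**
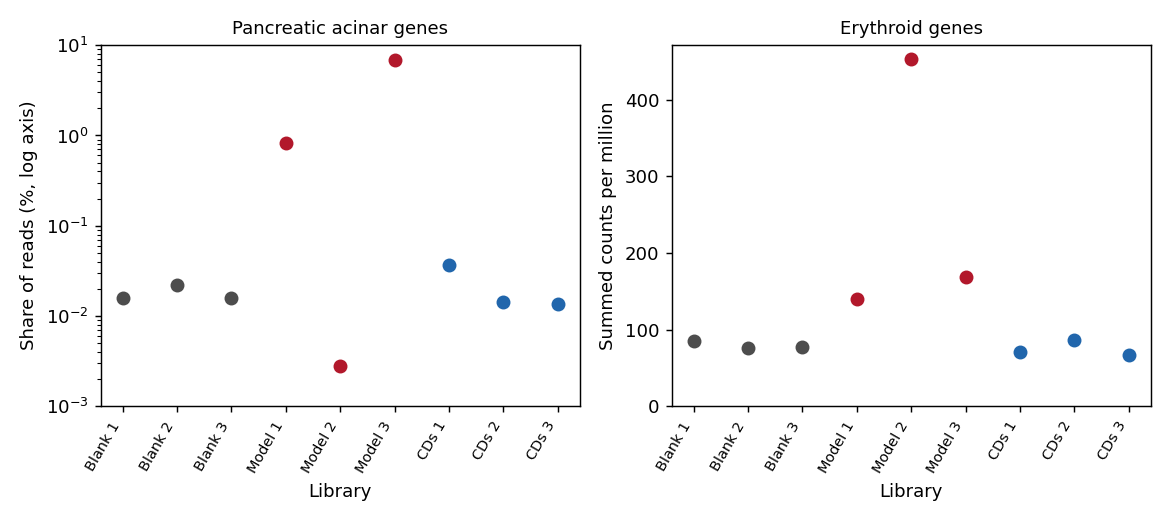
Share of reads from the pancreatic acinar list (left, percent on a log axis) and summed CPM of the erythroid list (right, linear axis from 0), 1 point per library (grey, Blank; red, Model; blue, CDs). Acinar transcripts reach 6.86% in Model 3, and erythroid transcripts lie between 140.6 and 452 CPM in Model and between 66.5 and 86.9 CPM in CDs.

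The second comparison, CDs versus Model, asks what differed in DSS-treated colon when carbon dots were given. No gene passed the test: edgeR called 0 of 14921 genes, the smallest adjusted p being 0.891, and 788 genes had an unadjusted p under 0.05 (228 higher and 560 lower in CDs), beside 746.1 expected by chance. That number was 1966 without Model 1 (smallest adjusted p = 0.0569) and 1549 without CDs 1 (0.441), and 491 without Model 2 (0.245) and 499 without Model 3 (0.9996). DESeq2 called 50 genes, 5 higher and 45 lower, and limma on FPKM called 0. Without Model 1, Model 3 and CDs 1, the libraries with pancreatic transcripts, edgeR called 1241 genes, 752 higher and 489 lower, in a comparison of CDs 2 and CDs 3 with Model 2 alone, which is assumed to vary like the other groups. Hemoglobin and heme synthesis transcripts were among the lowest in CDs: Hbb-bs was at 120.1 ± 108.0 CPM in Model and 15.1 ± 5.58 CPM in CDs (SD, n = 3 each), a log2 fold change of -2.99 ± 0.60 (SE; edgeR adjusted p = 0.891, DESeq2 adjusted p = 1.25e-04), and Alas2, the first enzyme of heme synthesis in red cell precursors, had a log2 fold change of -3.29 ± 0.63 (edgeR adjusted p = 0.891, DESeq2 adjusted p = 2.99e-04). Without Model 2 the log2 fold change was -1.94 for Hbb-bs and -2.22 for Alas2. The groups did not overlap for 7.99% of genes, beside 10% by chance.

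Among the lists, camera with its preset correlation called 18 of 41, 7 higher and 11 lower in CDs, while 0 were called with an estimated correlation and 0 with fry (smallest adjusted p = 0.143 with an estimated correlation, and 0.104 with fry). The erythroid list had a median log2 fold change of -2.88 over 7 genes, none called over all genes and 5 called lower when adjusted over the list alone (camera adjusted p = 3.05e-09; adjusted p = 0.143 with an estimated correlation). In Model versus Blank the same list had been higher, with 5 of 7 genes called (camera adjusted p = 0.0459; adjusted p = 0.458 with an estimated correlation). Summed erythroid transcripts were at 79.5 ± 4.99 CPM in Blank, 254 ± 172 CPM in Model and 74.97 ± 10.7 CPM in CDs (SD, n = 3 each; exact permutation test of CDs against Model, two-sided p = 0.1, the smallest possible).

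Remodelling lists were lower in CDs by the preset test. Metalloproteinases and inhibitors had a median log2 fold change of -0.74, with 14 of 15 negative and 3 called adjusted over the list alone, and extracellular matrix genes one of -0.39, with 24 of 26 negative and 0 called. Values were -2.02 ± 0.44 for Mmp10, -1.80 ± 0.45 for Mmp13, -1.31 ± 0.35 for Tnc and -1.11 ± 0.27 for Col12a1 (log2 fold change ± SE; edgeR adjusted p = 0.891 each). Adipocyte markers were negative in 11 of 11 members with a median of -1.11, and 6 were called adjusted over the list alone. Model 1 and Model 3 also carried pancreatic transcripts. The camera adjusted p was 3.77e-08 for metalloproteinases, 4.39e-09 for matrix and 4.39e-09 for adipocytes. With an estimated correlation adjusted p = 0.728 for the first 2 and adjusted p = 0.626 for adipocytes, and without the 3 libraries with pancreatic transcripts the adipocyte list had a camera adjusted p of 0.0531.

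Inflammatory cytokines had a median log2 fold change of -0.45, with 11 of 16 negative and 2 called adjusted over the list alone (camera adjusted p = 0.00549; adjusted p = 0.728 with an estimated correlation). Its camera adjusted p was 0.197 without Model 2, 0.235 without CDs 2 and 0.267 without CDs 3. Il11 was at 139 ± 84.7 CPM in Model and 33.5 ± 19.2 CPM in CDs, Il19 at 2.24 ± 0.993 and 0.451 ± 0.0853 CPM, and Il6 at 37.9 ± 21.6 and 16.2 ± 7.99 CPM (SD, n = 3 each). Chemokines, NF-kB, JAK-STAT3, neutrophil, macrophage, goblet cell, colonocyte, stem cell, antioxidant and ferroptosis lists were not called with all libraries. With 1 library left out, the JAK-STAT3, stem cell and antioxidant lists were still not called. Without CDs 1 camera called colonocyte (adjusted p = 9.25e-06) and goblet cell genes (0.0242) higher in CDs and neutrophil markers (0.0127), chemokines (0.0194) and NF-kB genes (0.0391) lower. Without Model 1 it likewise called colonocyte (adjusted p = 3.69e-05) and goblet cell genes (0.0227) higher and neutrophil markers (0.00825) lower, and ferroptosis genes (0.0418) lower. Without Model 2 it called neutrophil (adjusted p = 7.69e-05) and macrophage markers (0.0132) higher and goblet cell genes (0.0102) lower. Goblet cell genes were also lower without CDs 3 (adjusted p = 0.0421), and macrophage markers also higher without Model 3 (0.0158) and CDs 3 (0.0353). Reg3b, an antimicrobial lectin, had a log2 fold change of -3.83 ± 1.30 (edgeR adjusted p = 0.904) and was 1 of the 42 genes that followed the pancreatic reads, at 121 CPM in Model 1, 41.9 in Model 2 and 777 in Model 3, beside 8.25 to 30.0 CPM in CDs. Lists higher in CDs by the preset test included squamous epithelium markers (median 1.05, 9 of 9 positive, Krt14 at 2.12 ± 0.60), smooth muscle markers (median 0.48, 17 of 18 positive) and oxidative phosphorylation genes (median 0.16, 27 of 28 positive). Their camera adjusted p was 4.63e-04, 0.00178 and 1.80e-04, and adjusted p = 0.143, 0.807 and 0.801 with an estimated correlation. The squamous list had a camera adjusted p of 0.351 without the 3 libraries with pancreatic transcripts. The smooth muscle list had a camera adjusted p of 0.310 without CDs 2 and 0.182 without CDs 3, and oxidative phosphorylation genes of 0.217 without Model 3 and 0.115 without CDs 2.

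Of the other lists called by the preset test in CDs versus Model, inflammasome (median 0.28), interferon-stimulated (0.15), B cell (0.54) and tight junction genes (0.22) were higher. Coagulation (-0.33), endothelial (-0.16), neuron and glia (-0.23), hypoxia and glycolysis (-0.08), unfolded protein response (-0.07) and pancreatic acinar genes (-7.82, 12 of 12 called adjusted over the list alone) were lower. The acinar genes made up 6.86% of reads in Model 3, 0.833% in Model 1 and 0.00279% in Model 2. Without Model 3 the camera adjusted p of that list was 0.00235. Each of the lists named here had an adjusted p from 0.728 to 0.897 with an estimated correlation. Without Model 2 all but the B cell and acinar lists lost their call, the interferon-stimulated genes turning negative (camera adjusted p = 0.0861), and B cell markers turned negative without CDs 1 (camera adjusted p = 0.423) and lost their call without Model 1 (0.406). At 3 libraries per group simulated changes of 2-fold were recovered in 46% of genes and of 4-fold in 96%. Those libraries lacked variation that many genes share, so these shares do not show what the test could recover in the real ones.

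The third comparison, CDs versus Blank, asks which differences from untreated colon were present with DSS and carbon dots together. Monocyte and macrophage markers rose in 19 of 20 members, neutrophil markers rose in 18 of 21 and fell in 1, metalloproteinases rose in 15 of 15, and B cell markers rose in 13 of 13 (8 of 13 in Model versus Blank). B cell scores (mean log2 CPM less the Blank mean) were 2.80, 1.12 and 1.46 in CDs 1 to CDs 3, beside 1.05 to 1.69 in Model. Of 28 oxidative phosphorylation genes 14 fell, of 15 stem cell genes 9 fell and 2 rose, and none of 7 erythroid genes was called. In all 5309 genes were called, 3256 higher and 2053 lower, and the groups did not overlap for 54.1% of genes, beside 10% by chance. Camera adjusted p was 6.57e-12 for macrophages, 1.75e-09 for neutrophils, 6.84e-10 for metalloproteinases, 1.44e-04 for B cells, 4.35e-07 for oxidative phosphorylation and 0.00107 for stem cells. With an estimated correlation adjusted p = 0.333 for macrophages and stem cells, adjusted p = 0.383 for neutrophils, adjusted p = 0.355 for metalloproteinases and adjusted p = 0.540 for the other 2. Camera did not call the adipocyte (adjusted p = 0.101, and 0.0233 without Blank 3 and 0.0223 without CDs 3), hypoxia and glycolysis (0.229), unfolded protein response (0.134), pancreatic acinar (0.656) and erythroid (0.656) lists, which it called in Model versus Blank, and it called immediate early genes (adjusted p = 0.0223, and 0.107 without CDs 3; adjusted p = 0.540 with an estimated correlation), which it had called there without Model 1 (adjusted p = 0.0113) but not with all libraries (0.0814). Mitochondrially encoded genes had a median log2 fold change of -0.43, beside -0.64 in Model versus Blank, and the list was called lower (camera adjusted p = 0.0103, and 0.0880 without CDs 1; adjusted p = 0.540 with an estimated correlation), with none of 13 members called beside 6 in Model versus Blank. Whether the Model and CDs libraries differ in these lists is the question of CDs versus Model. Without Blank 2 the number called was 3398, and without Blank 2 and Blank 3, which carried prostate transcripts, it was 465.

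**Figure D3:**
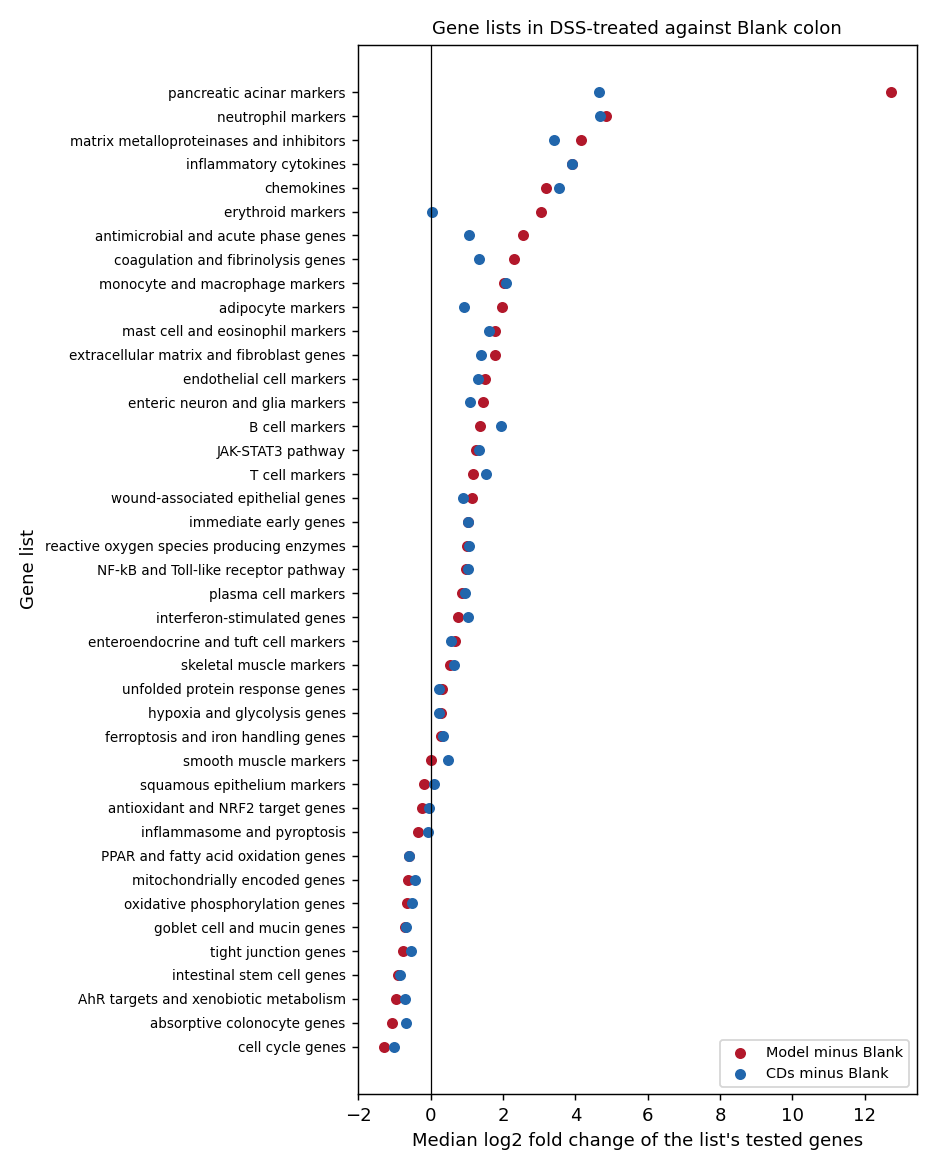
Median log2 fold change against Blank of the tested genes of each of the 41 lists, in Model (red) and in CDs (blue), with genes that had no read in 1 group set to their bound. The erythroid list lies at 3.05 in Model and at 0.02 in CDs, and the 2 medians are within 0.2 of each other for lists such as macrophage markers (2.03 and 2.07).

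Of the 3654 genes higher in Model than in Blank, 2941 were also called higher in CDs than in Blank, and of the 2920 lower genes 1841 were also called lower. Independent lists of these sizes would share 797.4 and 401.8 genes, and libraries simulated without any effect shared 0. At most 1 gene was called in those simulations, so their 0 is no guide to what the shared Blank libraries add, and part of the excess may come from them. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a correlation of 0.93, beside 0.51 simulated without any effect, and a covariance of 1.26, beside 0.06. No gene was called in opposite directions. For genes higher in Model, the median share of the log2 change from Blank that was left in CDs was 87.2% (quartiles 72.8% and 102.4%), and for genes lower in Model it was 83.7% (69.9% and 98.6%). Genes chosen for their change in the Model libraries would tend to show a smaller change in other libraries without any effect of the carbon dots. The size of that fall was not simulated, so the share is a description. By library it was 92.7%, 89.9% and 78.4% in CDs 1, CDs 2 and CDs 3 for higher genes, and 107.1%, 82.9% and 68.4% for lower genes. The Model libraries, on which the genes were chosen, ranged from 79.8% to 115.6% and from 73.5% to 118.7%, with Model 1 lowest, and CDs 3 lay below both ranges. The group median was 78.4% for higher genes without Model 1 and 94.0% without Model 2.

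With 0 genes called by edgeR in CDs versus Model (788 at an unadjusted p under 0.05), 0 of the genes called in Model versus Blank were called there with the opposite sign, and by DESeq2 it was 36. Across genes, which are not independent replicates, the log2 fold changes of these comparisons had a covariance of -0.22, beside -0.06 in simulations in which CDs libraries equalled Model, since both comparisons use the same Model libraries. The correlation was -0.49, beside -0.15 in the same simulations and -0.49 in simulations without any effect. Leaving out the 42 genes that followed the pancreatic reads, the covariance was -0.13 beside -0.04, a difference of -0.09. With the variance of the Model mean in place of the simulation the difference was also -0.09, and by that measure it was 0.00 without Model 2, -0.02 without Model 3, -0.01 without CDs 3, -0.17 without CDs 1 and -0.24 without Model 1.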

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

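Tests without the libraries holding pancreatic or prostate transcripts, and with the pancreatic level as a covariate, were chosen after seeing the data. Model versus Blank called 6574 genes, 3417 with a fold change of at least 2 and 1536 without the 2 libraries with prostate transcripts. CDs versus Blank called 5309, 2734 and 465 in the same order. CDs versus Model called 0 genes with edgeR, 50 with DESeq2 and 1241 without the 3 libraries with pancreatic transcripts, which leaves 1 Model library. With an estimated correlation 0 lists were called in each comparison, and with fry 26, 0 and 24. With DESeq2, 36 genes were called in opposite directions in Model versus Blank and CDs versus Model, beside 0. Leaving out each library gave 4405 (no Model 3) to 7459 genes for Model versus Blank, 0 to 0 for CDs versus Model and 3398 (no Blank 2) to 5540 for CDs versus Blank. Lists ranged from 31 to 33, 13 to 26 and 24 to 30, opposite calls from 0 to 0, and the share left in CDs from 78.4% to 94.0% for higher and from 67.2% to 93.0% for lower genes. With the replicate block the counts were 5672, 0 and 4475, and 4 of 9 libraries correlated best with one of their own number, beside 3 expected by chance. Of 171 named genes called in Model versus Blank, 88 were called in every alternative fit that tested them, the fold change limit not being counted. Without the pancreatic libraries Ctrl and Clps reversed in Model versus Blank (-0.46 and -2.00) and A4gnt in CDs versus Model (2.62). A list was counted as reversed only if it was called in at least 1 of the 2 fits compared, so turns of lists called in neither are not counted. For CDs versus Model the direction of 7 lists reversed in this sense with 1 library left out, the camera adjusted p ranging from 0.00370 (no CDs 1, reversed) to 0.910 for PPAR genes, from 5.04e-05 to 0.524 for interferon-stimulated genes (reversed without Model 2, 0.0861), from 7.69e-05 (no Model 2, reversed) to 0.708 for neutrophil markers, from 0.0102 (no Model 2, reversed) to 0.976 for goblet cell genes, from 0.0391 (no CDs 1, reversed) to 0.910 for NF-kB genes, from 9.59e-06 to 0.423 (no CDs 1, reversed) for B cell markers and from 1.65e-08 (no CDs 1, reversed) to 0.682 for cell cycle genes. PPAR genes also reversed without Model 1 (0.0285) and goblet cell genes without CDs 3 (0.0421). Without the pancreatic libraries the lists of NF-kB (0.00387), B cell (0.398), plasma cell (0.0245) and PPAR genes (6.21e-06) reversed. The cause was not tested. Alternatives for a table with FPKM alone did not apply. In simulations at this depth, with genes drawn independently, 4% (CDs versus Model) to 12% (Model versus Blank) of 1.5-fold changes were recovered.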

Other observations

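The pathway and added marker tests, and the tests on pancreatic and erythroid transcripts, the exchanged labels and the splits, were chosen after the results were seen, while the share of genes that follow the pancreatic reads was set beforehand. Among pathways written in the deposited table, genes called higher in Model than in Blank were enriched for complement and coagulation cascades (45 of 63 genes, one-sided Fisher's exact test adjusted over 318 pathways, adjusted p = 1.02e-11) and ECM-receptor interaction (48 of 80, adjusted p = 1.07e-08), and genes called lower for valine, leucine and isoleucine degradation (33 of 47, adjusted p = 4.33e-12), the citrate cycle (25 of 30, adjusted p = 4.62e-12) and butanoate metabolism (17 of 21, adjusted p = 7.85e-08). Expected counts for these 5 pathways were 16.7, 21.2, 9.10, 5.81 and 4.07 in the order given. In all, 87 pathways passed for higher and 45 for lower genes. The pathway test treats genes as independent and allows for no correlation between them, so its p-values do not measure variation between libraries. Of 8 mesothelial genes, known from the serosal lining, 5 rose in Model against Blank, among them Msln with a log2 fold change of 3.45 ± 0.78 (edgeR adjusted p = 0.00781), Wt1 with 3.33 ± 0.81 (edgeR adjusted p = 0.0106) and Muc16 with 2.37 ± 0.57 (edgeR adjusted p = 0.0104). The other 3 were not called, with Upk3b at 1.10 ± 0.66, Upk1b at -0.26 ± 0.41 and Krt19 at -0.74 ± 0.33. Model 2 was the highest Model library for both Msln and Wt1. Before TMM scaling Msln was at 6.62, 29.4 and 3.33 CPM and Wt1 at 1.58, 6.27 and 2.22 CPM in Model 1, Model 2 and Model 3. In CDs against Blank 6 of the 8 mesothelial genes rose. Pyy and Sst, gut hormones, rose in Model by 1.07 ± 0.17 and 1.66 ± 0.25 on the log2 scale (edgeR adjusted p = 0.00173 and 0.00120), as did the islet and gut hormones Ppy by 1.79 ± 0.23 and Gcg by 1.23 ± 0.28 (edgeR adjusted p = 6.14e-04 and 0.00794).

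Over 12 acinar genes the log2 ratio of Model 3 to Model 1 had an SD of 0.17 around a median of 3.05, a ratio that could have differed from gene to gene and that pancreatic tissue carried into both samples predicts. The log2 ratio of Model 3 to CDs 1 had an SD of 0.57 around a median of 7.59, which leaves carry-over into CDs 1 open. Induction of these genes in the colon by DSS would raise them in every DSS-treated library, but 3 of the 6 were at or below the highest Blank library. In those 3, most acinar reads were of Cela1, and Cpa1, Cela2a, Cela3b and Pnlip had no read. Reads passing from Model 3 into Model 1 would carry insulin with them: 11.2 insulin reads were predicted from the 102 in Model 3, and 1 was counted (exact binomial test, two-sided p = 4.24e-04). That p covers counting error only and rests on 1 read, near the floor, so passed reads stay open beside carry-over of pancreas at dissection, a hypothesis.

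In each of the 3 comparisons 10 splits of the 6 libraries into 3 and 3 are possible, too few for a share under 0.05. For Model versus Blank the real split called 6574 genes and the highest other 0 (1 of 10 splits gave as many), and for CDs versus Blank 5309 and 0 (1 of 10). For lists the values were 33 and 28 (1 of 10) in Model versus Blank and 29 and 25 (1 of 10) in CDs versus Blank. For CDs versus Model the real split called 0 genes, so that 10 of 10 splits gave as many, and 18 lists, which 5 of 10 splits reached, the highest other calling 25.

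Exchanging Model 1 and CDs 1 called 1804 genes, where the real grouping and every other CDs versus Model split called 0. This split was singled out by that count, so the count is no test of it. The calls may point to a structure of the 6 DSS-treated libraries other than their groups. The tables argue against pancreatic reads as its cause. The side of Model 2, Model 3 and CDs 1 held the highest share of them (6.86%, Model 3). It also held Model 2, which had no read of Cpa1, Cela2a, Cela3b or Pnlip. Of 9 pairs of libraries across the sides, that side had the higher share in 5. In Model 2, CDs 2 and CDs 3 most of the share was Cela1, which Blank libraries also held. Pairs of Model 2 with CDs 2 and CDs 3 thus say little about pancreatic reads. The other side also mixed libraries with and without them, Model 1 holding 0.833%. Of the 1804 genes 0% followed the pancreatic reads, which decides nothing. Genes that follow them differ widely between Model 3 and Model 2, on the same side, and 42 such genes could not pass 2.33%. Principal components and distances come from the same expression values as the split, so they are not separate evidence for it. On the first principal component Model 1 (26.4) lay beside CDs 2 (25.2) and CDs 3 (11.7), and CDs 1 (58.8) beside Model 2 (62.0) and Model 3 (63.2). On the second, Model 1 (31.6) lay nearer Model 3 (46.7) than CDs 2 (-32.4) and CDs 3 (-27.3). By Euclidean distance the library nearest Model 1 was Model 3 (60.7, beside 71.6 to CDs 3), and Model 3 was also nearest CDs 1 (73.4). Other values followed the labels: squamous epithelium scores (mean log2 CPM less the Blank mean) were -0.63, -0.12 and -0.65 in Model 1 to Model 3 and 0.51, 0.44 and 0.49 in CDs 1 to CDs 3, and erythroid transcripts were at 140.6 CPM in Model 1 and 71.5 CPM in CDs 1, beside 452 and 169 CPM in the other Model and 86.9 and 66.5 CPM in the other CDs libraries. Exchanged labels and an untested difference between animals in the strength of the injury cannot be told apart, because these values point both ways, the lists were singled out for differing between the labelled groups, and no record outside expression was analysed here.

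Erythroid transcripts were lower in CDs than in Model. The single library Model 2, the highest, is not the whole cause: without it the median log2 fold change of the list was -1.94. Reads shared between near-identical hemoglobin genes are not the cause either, since Alas2, which has no such copy, had a log2 fold change of -3.29 ± 0.63 (-2.22 ± 0.35 without Model 2). Less blood of every kind may be part of it: platelet genes had a median of -0.36, ranging from -1.85 to 0.45. Summed platelet genes were at 30.4, 103.6 and 40.4 CPM in Model 1 to Model 3, beside 29.4 to 39.7 CPM in CDs. Outside Model 2 the platelet sums of the groups overlapped, while erythroid sums did not (140.6 and 168.9 CPM in Model, 66.5 to 86.9 CPM in CDs). For Model 1 and Model 3 the platelet sums thus show no sign of less blood of every kind in CDs. For Model 2 it stays open. An effect of the carbon dots on bleeding or red cell production also stays open as an untested hypothesis, with no erythroid gene called by edgeR.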
